A study of Mus musculus with 9 samples.

How the data were processed

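Total RNA of mouse tibiae was enriched for polyadenylated RNA with oligo(dT) beads, made into libraries with the NEBNext Ultra RNA kit and sequenced on an Illumina instrument, per the labels' protocols. The kit does not mark the strand of a transcript, so reads of genes that overlap on opposite strands cannot be told apart. The submitters' processing notes name fastp, StringTie 1.3.1, RSEM, DESeq2 and edgeR, without their role or order. The aligner, genome build and annotation release are not given in the sources used here, so no coordinates are given.

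The authors deposited a table of 22183 genes with an estimated count and an FPKM value for each of the 9 libraries; the estimated counts need not be whole, and they were rounded to whole numbers here before any test. The FPKM values, also as deposited by the authors, are fragments per kilobase of transcript, scaled to library depth. They served for the named-gene rule and for an alternative test. Gene symbols came from the deposited table, in which 13 genes have none, and 22128 of the gene identifiers occur in GENCODE mouse release 21, which was used only to find overlapping genes and the GC content of transcripts. Transcript length was taken from the ratio of counts to FPKM, as the median over libraries. For 34.6% of genes this ratio gave the same length within 1% in all libraries with at least 100 counts, so the length is itself an estimate. Values of a gene whose exons overlap those of another on either strand, or that shares sequence with a near-identical copy, are uncertain, and the report says once which of the genes it names these are.

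Groups and replicate numbers came from the sample titles: naive, Ti and Ti+I-OG, 3 libraries each. Pairs of libraries in a group differed far beyond counting noise (chi-square per degree of freedom 13.1 to 136), so none was a copy of another and all were kept. This cannot show that they are separate samples, since libraries prepared from the same sample can also exceed counting noise. Of the 22183 genes, 4425 had no count in any library, and edgeR's filterByExpr kept 14211 genes and left out 7972. With total counts of 16256081 to 24766502, 3 counts, the floor for a gene with no count, correspond to 0.114 to 0.206 CPM. Intervals and floors cover counting error only and leave out the spread between libraries. They treat reads as independent, which PCR copies are not, so the intervals may be too narrow and the floors too low.

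Genes were tested with edgeR 4.0.16 (R 4.3.3), using TMM normalisation and the quasi-likelihood test. A single fit of all 9 libraries with a mean per group had 6 residual degrees of freedom. It gave the contrasts Ti vs naive, Ti+I-OG vs Ti and Ti+I-OG vs naive and an F test over the 3 groups. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over the 14211 genes, with a threshold of 0.05. Log2 fold changes come from this fit and their SE is the fold change divided by the square root of the F statistic. CPM values are TMM-normalised, given as mean ± SD over 3 libraries. Where a called gene named by the rule had 5 counts or fewer in a group, the ratio of pooled counts is given with its exact 95% interval for counting error.

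Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation was the alternative, as was the rotation test fry, which asks whether a list's genes move on balance, or in either direction, without comparing them with other genes. The 32 lists cover osteoclasts, osteoblasts and bone matrix, osteocytes, chondrocytes, tendon and fibrous tissue, fibrillar matrix, integrins and focal adhesion, the Wnt pathway, inflammatory mediators, the RANKL axis, macrophages, alternative macrophage activation, neutrophils, erythroid cells, megakaryocytes, the B lineage, plasma cells, T and NK cells, mast cells with eosinophils and basophils, skeletal muscle, adipocytes, endothelium, Schwann cells and nerve, skin and hair, proliferation, interferon-stimulated genes, immediate early genes, oxidative phosphorylation, glycolysis and hypoxia, oxidative stress, bone morphogenetic protein and TGF-beta signalling, and irisin. Some genes are in more than 1 list, for example 6 of the RANKL axis and 4 of the irisin list. KEGG pathways with 15 to 500 tested genes, 324 in all, were tested the same way. The level of a list in a library is the mean over its genes of log2 CPM, relative to each gene's mean over the 9 libraries.

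Named genes followed a rule. Among genes with a proper symbol, a mean FPKM of at least 1 in either group, an adjusted p under 0.05 and no overlap between the libraries of the groups, the 8 with the largest positive and the 8 with the largest negative fold change were taken. Where fewer passed, those were taken, and where none passed, the 4 with the smallest p, said not to pass. Up to 4 members of each list with the smallest p in the list's direction were added, and in every comparison Fndc5, Itgav, Itgb5, Tnfsf11, Tnfrsf11b, Acp5, Ctsk, Bglap, Sost, Tnf, Il1b and Il6, together with genes called in opposite directions by Ti and by Ti+I-OG. The text gives 2 to 4 of these members per list. The mast cell genes Mcpt4, Tpsb2 and Cma1 in Ti vs naive, the genes called upward in both steps, and the other members named where 5 or fewer genes of a list rose or fell (for example Fgf23, Cd163, Il4ra and Tlr4) were named after their values were seen.

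The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom with sample weights, limma-trend on log2(FPKM + 1) for genes with FPKM of at least 1 in 3 libraries, no filter on low counts, a mean of at least 100 counts, normalisation without muscle genes, only the 6 libraries of a comparison, the replicate number as a block, at least a 2-fold change, and each library left out in turn. After seeing the data, a robust variance fit, normalisation without erythroid genes, and a correction for transcript length (a lowess curve of span 0.3 against length in each library), with and without the block, were added.

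Whether the replicate numbers pair samples was checked by correlating the deviations of same-numbered libraries from their group means across genes. The correlations for replicates 1, 2 and 3 were 0.197, 0.115 and 0.273 between naive and Ti+I-OG, all above 0.1, so the blocked values are given for that comparison. In the other comparisons not all were above 0.1. No label pairs the samples, and 3 correlations per comparison cannot establish that the numbers do.

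Comparisons that share libraries were set against 100 simulated draws of unchanged groups. The tests were checked on simulated counts with 200 changed genes, 100 each changed 2-fold and 4-fold. For Ti vs naive edgeR recovered 64% of the 2-fold and 97% of the 4-fold changes, and 6 of its 167 calls were false (14076 genes). The values were 64%, 96% and 12 of 172 calls (14076 genes) for Ti+I-OG vs Ti. For Ti+I-OG vs naive they were 68%, 96% and 11 of 175 calls (14086 genes). In the same order, false calls were 22 of 191, 30 of 200 and 33 of 207 for DESeq2 and 8 of 164, 11 of 166 and 9 of 170 for limma-voom. The simulated genes varied independently, and only genes above a minimum CPM were changed. These rates may therefore be too favourable for the real libraries. No sample treated with hydrogel alone was analysed here.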

Results

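Polyadenylated RNA of mouse tibiae was sequenced in 9 libraries, 3 in each of 3 groups. The naive group received no treatment, the Ti group received titanium particles, and the Ti+I-OG group received titanium particles and I-OG, an injectable hydrogel of natural polymers loaded with irisin. Irisin is a peptide hormone released by muscle and cleaved from the protein encoded by Fndc5. Wear particles from implants are used to model aseptic loosening, the loss of an implant's hold in bone without infection. The tibiae of hydrogel-treated mice were taken after 5 weeks of treatment. The labels give no such time for the naive and Ti groups, so the groups may also differ in time. The total count per library, for replicates 1 to 3, was 24766502, 20636647 and 21818941 in naive and 20982874, 24049496 and 20164092 in Ti. In Ti+I-OG it was 21998585, 16256081 and 18072650. No label states that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

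The makeup of the libraries differed between groups. The α- and β-globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which mark red cell precursors, took 6.15% ± 3.26 of counts in naive, 8.04% ± 1.72 in Ti and 15.6% ± 0.470 in Ti+I-OG (SD, n = 3 each). The 30 skeletal muscle genes took 0.356% ± 0.168, 0.786% ± 0.452 and 0.685% ± 0.176, and mitochondrially encoded genes 5.73% ± 1.23, 9.36% ± 3.13 and 6.76% ± 0.891, in the same order. The first principal component carried 45.1% of the variance and placed the naive libraries at −39.8, −19.3 and −67.6, the Ti libraries at 24.7, 47.9 and −1.82, and the Ti+I-OG libraries at 19.6, 30.3 and 6.17. Naive replicate 3 stood apart in bone and B cell genes: Bglap, which encodes osteocalcin, was at 12.4 normalised CPM there and at 141 and 164 CPM in the other naive libraries. Bglap shares sequence with near-identical copies, so its values are uncertain throughout.

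The first comparison set tibiae given titanium particles against untreated ones. As naive tibiae received no treatment, the particles cannot be told apart from the procedure that delivered them. In Ti tibiae 13 of 14 tendon and fibrous tissue genes, 13 of 18 bone matrix genes, 9 of 11 osteocyte genes and 6 of 16 osteoclast genes rose. Tested as sets, these lists passed with the preset but not with an estimated correlation (adjusted p = 0.262 to 0.408). Each also passed the directional fry test, which does not compare a list with other genes (adjusted p = 0.00287 to 0.0172). Tnmd, which encodes the tendon membrane protein tenomodulin, rose by a log2 fold change of 3.99 (SE 0.334, adjusted p = 0.00098), from 0.635 to 10.2 CPM on average. Mmp12, a macrophage metalloelastase, rose from 2.74 ± 0.423 to 71.9 ± 50.9 CPM (SD, n = 3; log2 fold change 4.71, adjusted p = 0.00318). Ctsk, the main collagen-degrading protease of osteoclasts, rose from 241 ± 61.7 to 738 ± 67.0 CPM (log2 fold change 1.62, SE 0.219, adjusted p = 0.00377), and Acp5, the osteoclast acid phosphatase, from 291 ± 49.6 to 759 ± 48.9 CPM (1.38, SE 0.209, adjusted p = 0.0065).

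Of the 14211 genes tested, 914 changed at an adjusted p under 0.05, 575 higher and 339 lower in Ti, and 492 of them changed at least 2-fold. The largest rises and falls given next are those among genes that met the naming rule's conditions on FPKM and overlap. The largest rises also included C1qtnf3 (log2 fold change 3.84, SE 0.733), Crabp2 (3.82, SE 0.925; 69 counts against 5, a ratio of 15 with a 95% counting interval of 6.13 to 47.7; not passing in 5 of 6 fits with a library left out, adjusted p up to 0.125) and Kera, the corneal and tendon proteoglycan keratocan (3.78, SE 0.496). Commd1b, Pagr1a and Ccl21b were also among the 8 largest rises under that rule, but they overlap or nearly match other genes and their values are uncertain. The largest falls under that rule were in Lipg, an endothelial lipase (−3.0, SE 0.541), the chemokine-like gene Prok2 (−2.93, SE 0.428), Ggt1 (−2.80, SE 0.342), Kcna3 (−2.09), Tgm1 (−2.03), Sema6b (−1.96), Ifitm1 (−1.94, SE 0.233) and Acod1, which makes itaconate in activated macrophages (−1.78, SE 0.179). Lipg varied widely in naive, at 52.2 ± 50.7 CPM, against 6.52 CPM in Ti. Naive replicate 3 held 111 CPM against 26.6 and 19.3 in the others, and without it Lipg was at −1.84 and still passed. It did not pass without Ti replicate 1 or 2 (adjusted p up to 0.0730). The libraries of the groups did not overlap for 27.2% of tested genes, where chance gives 10%.

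The skeletal gene lists were directed upward. Of 18 osteoblast and bone matrix genes 13 rose and 5 did not pass (17 rose when adjusted over the list alone), with Tnn at 2.65, Omd at 2.69, Bmp3 at 1.27 and Ibsp at 1.20. Tested as a set the list gave an adjusted p = 2.97e-10, and adjusted p = 0.364 with an estimated correlation. The list's mean log2 level was −1.77 in naive replicate 3, relative to the mean of all libraries, and −0.41 and −0.42 in the other naive libraries. Of 11 osteocyte genes 9 rose and 1 fell (10 and 1 adjusted over the list alone). Among those that rose were Dmp1 (1.09), Mepe (1.65), Fbln7 (2.68) and Sost, the osteocyte Wnt inhibitor sclerostin (1.32, SE 0.220), and the gene that fell was Fgf23, a phosphate-regulating hormone (−2.61). The set passed at 4.29e-07, with adjusted p = 0.262 with an estimated correlation. Of 16 osteoclast genes 6 rose and 10 did not pass (7 rose adjusted over the list alone), among them Atp6v0d2 (1.39) and the fusion gene Ocstamp (1.48). As a set they passed at 0.000314, with adjusted p = 0.408 with an estimated correlation. The larger KEGG pathway of osteoclast differentiation did not pass (121 genes, adjusted p = 0.462, 6 rose and 2 fell, median −0.08). All 16 cartilage genes had positive fold changes, 5 rose and 11 did not pass (15 rose adjusted over the list alone), with Comp at 2.07, Col2a1 at 1.93, Col11a1 at 1.94, Sox9 at 1.83 and Col11a2 at 1.10. The list's set test passed at 4.13e-06, with adjusted p = 0.476 with an estimated correlation. Of 28 genes of bone morphogenetic protein and TGF-beta signalling 3 rose, Tgfb2 (1.66), Tgfb3 (1.36) and Bmp4 (1.24), and 25 did not pass (10 rose adjusted over the list alone). Tested as a set, the list passed at 0.000356, with adjusted p = 0.321 with an estimated correlation.

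Among the 32 lists the largest median, 2.29, was that of tendon and fibrous tissue. Of its 14 genes 13 rose and 1 did not pass (14 rose adjusted over the list alone), among them Thbs4 (2.94), Fmod (2.47) and Angptl7 (2.33). The set passed at 2.33e-14, with adjusted p = 0.282 with an estimated correlation. Of 20 fibrillar and fibrosis-associated matrix genes 14 rose and 6 did not pass (18 rose adjusted over the list alone). Col3a1, the collagen III chain, rose from 55.3 ± 20.0 to 520 ± 204 CPM (log2 fold change 3.23, adjusted p = 0.00213), Mmp2 by 1.57 and Tnc by 0.86. The set passed at 4.28e-11, with adjusted p = 0.138 with an estimated correlation.

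**Figure D1:**
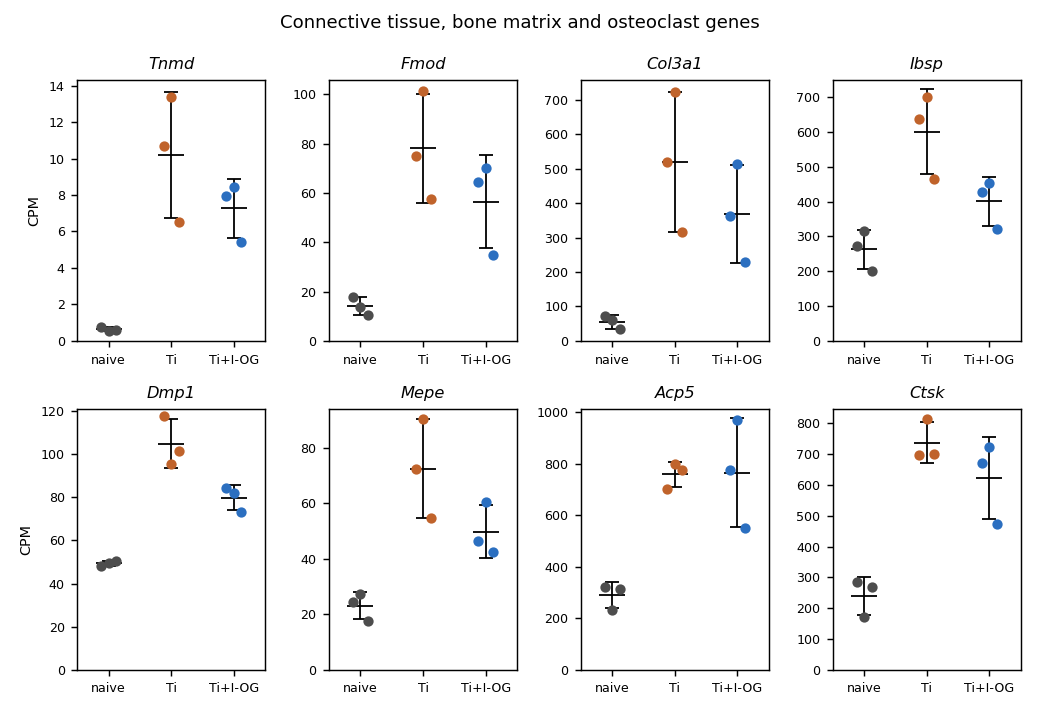
Normalised CPM (counts scaled to library size, linear axes from 0) of 8 tendon, matrix, bone and osteoclast genes in naive, Ti and Ti+I-OG tibiae; each point is a library, horizontal lines are group means and bars are SD (n = 3). Every Ti library lay above every naive library for these genes, for example Ctsk at 738 ± 67.0 against 241 ± 61.7 CPM.

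The series' design text names integrin, Wnt and inflammatory pathways. Of 39 integrin and focal adhesion genes 5 rose and 34 did not pass (6 rose adjusted over the list alone). Itgav, the integrin αV chain, rose by 1.04 (SE 0.189, adjusted p = 0.0139), Fermt2 by 1.26, Parva by 1.15, Itgb8 by 1.73 and Itga10, whose value is uncertain because it overlaps another gene, by 0.91, whereas Itgb5 was at 0.16 (SE 0.144, adjusted p = 0.502). The set did not pass (adjusted p = 0.489), and its median of −0.04 and mean of 0.14 differed in sign. Of 57 Wnt pathway genes 9 rose and 48 did not pass (15 rose and 2 fell adjusted over the list alone). The secreted Wnt modulators Sfrp2 (3.22, SE 0.414) and Dkk3 (2.3) rose, as did the ligand Wnt5b (1.47), and the set passed at 4.07e-06, with adjusted p = 0.416 with an estimated correlation. None of 37 inflammatory cytokines and mediators passed edgeR's test, over all genes or adjusted over the list alone; 8 had an unadjusted p under 0.05, and DESeq2 called 2, limma-voom 3 and limma-trend on FPKM 0. The log2 fold changes were −0.60 for Tnf (SE 0.355, adjusted p = 0.295), −0.21 for Il1b (SE 0.445, adjusted p = 0.788) and −0.71 for Il6 (SE 0.607, adjusted p = 0.474), and the set's adjusted p was 0.684 with a median of −0.01 and a mean of 0.18. Of 16 genes of the RANKL axis Trem2 rose (1.05, adjusted p = 0.0167) and 15 did not pass (1 rose adjusted over the list alone). Tnfsf11, which encodes RANKL, was at 0.77 (adjusted p = 0.222) and its decoy receptor Tnfrsf11b at 1.26 (adjusted p = 0.134). The RANKL set passed at 0.0446, with adjusted p = 0.416 with an estimated correlation. Fndc5 was at 1.54 (SE 0.547, adjusted p = 0.107). Of the 7 irisin-related genes Itgav alone rose, with 3 adjusted over the list alone, and the set passed at 0.0446, with adjusted p = 0.476 with an estimated correlation, but in 5 of 6 fits with a library left out it did not pass (adjusted p up to 0.138).

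Blood and marrow lists had few members that passed. Of 18 neutrophil genes 3 fell, Ctsg (−1.07), Prtn3 (−1.35) and Cxcr2 (−0.54), and 15 did not pass (3 fell adjusted over the list alone). Its set test passed at 0.00648, with adjusted p = 0.506 with an estimated correlation. All 12 megakaryocyte genes had negative fold changes and none passed, also adjusted over the list alone, for example Tubb1 (−0.84, adjusted p = 0.24). The set passed at 0.00648, with adjusted p = 0.515 with an estimated correlation. It did not pass without Ti replicate 2 (adjusted p = 0.200), where the list's mean log2 level was −1.48 against −0.28 and 0.45 in the other Ti libraries. None of 15 B lineage genes passed, also adjusted over the list alone, though all were positive, such as Cd79a (0.76, adjusted p = 0.112). As a set they passed at 0.000162, with adjusted p = 0.476 with an estimated correlation, and the list's mean log2 level was −1.37 in naive replicate 3 against −0.32 and 0.23 in the other naive libraries. Of 18 macrophage genes Trem2 (1.05), Cd68 (0.58) and Lyve1 (1.22) rose and Cd163 fell (−0.81), with 4 and 1 adjusted over the list alone. As a set they had an adjusted p = 0.0542. Of 11 genes of alternative macrophage activation Retnla (2.1), Cd209a (1.0) and Pparg (0.80) rose and Cd163 and Il4ra (−1.0) fell, with the same counts adjusted over the list alone (set adjusted p = 0.529). Of 12 mast cell, eosinophil and basophil genes the mast cell protease genes Mcpt4 (3.07), Tpsb2 (3.32) and Cma1 (2.58) rose and the eosinophil peroxidase gene Epx fell by 1.01, with 3 higher and 2 lower adjusted over the list alone. The set had an adjusted p = 0.784, a median of −0.25 and a mean of 0.45. The 19 erythroid genes (set adjusted p = 0.358) and the 17 T and NK cell genes (0.684) had no member that passed, also adjusted over the list alone. Of 10 plasma cell genes Sdc1 rose (0.95), also adjusted over the list alone (set adjusted p = 0.868).

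Other tissues and cell states completed the comparison. All 30 skeletal muscle genes had positive fold changes, Tnni1 (3.14; 44 counts against 5, a ratio of 9.57, interval 3.81 to 30.9) and Mylpf (1.75) rose and 28 did not pass (17 rose adjusted over the list alone). The list's set test passed at 8.52e-08, with adjusted p = 0.476 with an estimated correlation, where muscle genes took 0.786% of counts in Ti and 0.356% in naive. The libraries of the groups overlapped: the list's mean log2 level was 0.45, 1.08 and −0.64 in Ti replicates 1, 2 and 3 and −1.81, −0.34 and −0.50 in naive replicates 1, 2 and 3. Of 19 adipocyte genes Lpl (1.53), Scd1 (2.18) and Pparg (0.80) rose and 16 did not pass (9 rose adjusted over the list alone). Tested as a set, the list passed at 0.000484, with adjusted p = 0.476 with an estimated correlation. Of 10 Schwann cell and nerve genes Pmp22 (1.05) and Gldn (4.20; 95 counts against 5, a ratio of 20.7, interval 8.55 to 65.1; not passing in 4 of 6 fits with a library left out, adjusted p up to 0.113) rose, also adjusted over the list alone. Its set test passed at 0.0152, with adjusted p = 0.451 with an estimated correlation. No endothelial gene of 15 passed, also adjusted over the list alone (set 0.0446, adjusted p = 0.506 with an estimated correlation). No skin or hair gene of 6 did, and their set test (adjusted p = 0.723) was directed downward with a median of 0.02 and a mean of 0.03. Foxm1 fell (−0.80) among 25 proliferation genes (1 adjusted over the list alone; set 0.00286, adjusted p = 0.506 with an estimated correlation). Oas2 fell (−0.98) among 24 interferon-stimulated genes (1 adjusted over the list alone; set 0.0265, adjusted p = 0.476 with an estimated correlation). Atf3 rose (1.26) among 20 immediate early and stress genes (2 adjusted over the list alone; set 0.0443, adjusted p = 0.476 with an estimated correlation). None of 38 nuclear genes of oxidative phosphorylation passed, also adjusted over the list alone, while 36 were positive (set 0.000356, adjusted p = 0.476 with an estimated correlation). Of 18 glycolysis and hypoxia genes Bnip3 rose (1.05; 1 higher and 1 lower adjusted over the list alone), and the set, directed downward, passed at 0.0443, with adjusted p = 0.506 with an estimated correlation. Gpx3 (1.08) and Mt2 (0.91) rose among 15 oxidative stress genes, also adjusted over the list alone (set 0.0269, adjusted p = 0.476 with an estimated correlation). In the 8 lists with no member passing edgeR's test, 33 of 158 genes had an unadjusted p under 0.05, and DESeq2 called 5, limma-voom 14 and limma-trend on FPKM 0.

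In all, 23 of the 32 lists passed the set test with its preset correlation, 18 directed upward and 5 downward, and none passed with an estimated correlation. Of 324 KEGG pathways 34 passed, 18 upward and 16 downward, and again none with an estimated correlation (smallest adjusted p = 0.126). The directional fry test passed 8 pathways and 7 lists. These lists were osteoclast, bone matrix, osteocyte, tendon, fibrillar matrix, Wnt and bone morphogenetic protein. The count of 914 genes was 405, 1428 and 213 without naive replicates 1, 2 and 3, and 100, 105 and 1999 without Ti replicates 1, 2 and 3. In all 6 of these fits 25 of the 74 called genes chosen for naming passed, among them Tnmd, Mmp12, Ctsk, Acp5, Col3a1, Dmp1, Sfrp2 and Ifitm1. Other tools gave 1859 genes (DESeq2) and 2461 (limma-voom), and limma-trend on FPKM gave 566. Fold change and transcript length correlated at −0.240 (Spearman, across genes, which are not independent replicates). With a length correction the oxidative phosphorylation (adjusted p = 0.168), oxidative stress and immediate early lists (0.062 each) no longer passed, nor did 8 of the 74 named calls: Atf3, Ccl21b, Cd68, Mt2, Mylpf, Pagr1a, Pparg and Retnla. Acp5, Mmp12, Itgav, Sfrp2, Tnc, Tgfb2, Tgfb3, Bmp4, Prtn3, Mt2, Bnip3, Il4ra, Il1b and Tgm1 overlap a gene on the opposite strand and Col3a1 and Foxm1 one on the same strand, so their values are uncertain here and in the other comparisons.

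The second comparison set tibiae given titanium particles and the irisin hydrogel against tibiae given particles. No group given hydrogel without irisin was analysed, so irisin cannot be told apart from the gel or its injection. No label states what the Ti group received in place of the hydrogel. Of the 6 genes that changed, 5 were contractile genes typical of slow-twitch muscle fibres, higher in Ti+I-OG than in Ti. They are 5 of 14 genes in a slow-fibre list drawn up after the results were seen, of which 9 did not pass, 6 of them positive, and the planned list of 30 muscle genes did not pass as a set (adjusted p = 0.0989). Myh7 (ENSMUSG00000053093), the slow myosin heavy chain, was at 10.9 ± 0.600 CPM in Ti+I-OG and 0.573 ± 0.331 CPM in Ti (SD, n = 3; log2 fold change 4.21, SE 0.401, adjusted p = 0.00387). The slow troponin genes Tnni1 (ENSMUSG00000026418; 3.06, SE 0.365, adjusted p = 0.0198) and Tnnt1 (ENSMUSG00000064179; 1.55, SE 0.217, adjusted p = 0.0322) and the slow myosin light chain genes Myl3 (ENSMUSG00000059741; 2.95, SE 0.369, adjusted p = 0.0212) and Myl2 (ENSMUSG00000013936; 2.01, SE 0.281, adjusted p = 0.0322) also rose. Angptl4 (ENSMUSG00000002289), a secreted inhibitor of lipoprotein lipase, rose from 11.3 ± 0.383 to 23.2 ± 1.25 CPM (1.04, SE 0.134, adjusted p = 0.0213) and was at 21.1 ± 1.36 CPM in naive.

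**Figure D2:**
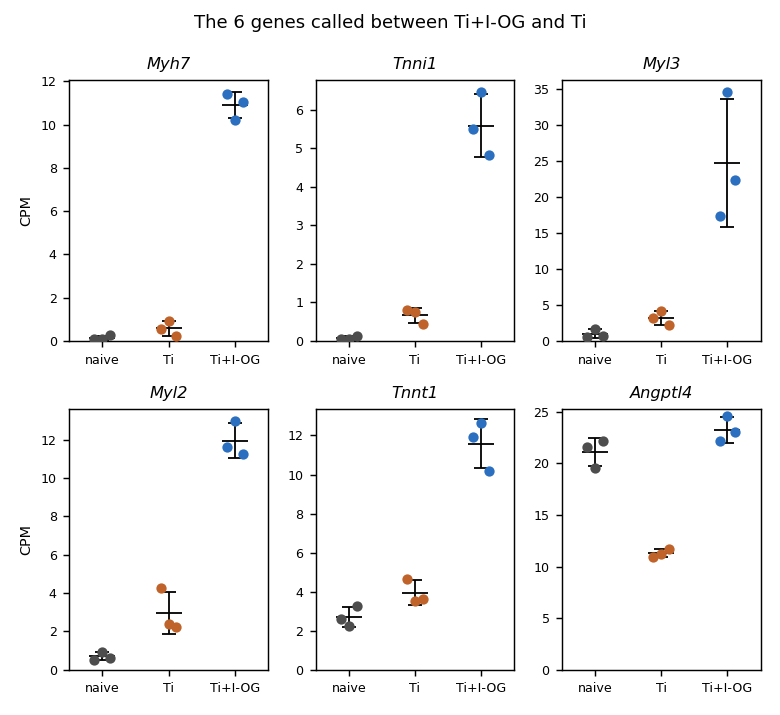
Normalised CPM (counts scaled to library size, linear axes from 0) of the 6 genes that passed between Ti+I-OG and Ti, in all 3 groups; each point is a library, horizontal lines are group means and bars are SD (n = 3). For each gene the 3 Ti+I-OG libraries lay above the 3 Ti libraries, as for Myh7 at 10.9 ± 0.600 against 0.573 ± 0.331 CPM.

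These 6 were the only genes of 14211 to pass edgeR's test, all higher in Ti+I-OG. In total 1114 genes had an unadjusted p under 0.05, and the groups did not overlap for 14.5% of genes, where chance gives 10%. No gene was lower in Ti+I-OG at the threshold, nor by limma-voom or limma-trend on FPKM, while DESeq2 called 5 lower and edgeR without Ti replicate 2 called 2 lower. The smallest unadjusted p among lower genes belonged to Ighg1 (−2.33, adjusted p = 0.345), Iglv1 (−0.85), Gpr141 (−0.71) and Rin2 (−0.56, adjusted p = 0.628 each). Myh7, Myl2 and Myl3 overlap genes on the opposite strand, which the unstranded libraries cannot separate, so their values are uncertain.

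Genes of the pathways named for the study did not pass singly. Itgav was at −0.48 (SE 0.187, adjusted p = 0.628) and Itgb5 at 0.04 (SE 0.144, adjusted p = 0.957). Tnf (0.47, adjusted p = 0.743), Il1b (0.07, adjusted p = 0.975) and Il6 (−0.06, adjusted p = 0.988) did not pass, nor did Acp5 (0.01, SE 0.205), Ctsk (−0.24, SE 0.214), Bglap (−0.61), Sost (−0.26), Tnfsf11 (−0.51), Tnfrsf11b (−0.53) and Fndc5 (0.13). The set tests for 39 integrin and focal adhesion genes (adjusted p = 0.103, median −0.10) and 37 inflammatory genes (adjusted p = 0.91) did not pass, and neither list had a called member, also adjusted over the list alone. The 57 Wnt pathway genes were lower as a set at 0.00165, with a median of −0.22 and no member passing, also adjusted over the list alone, and with adjusted p = 0.605 with an estimated correlation; Frzb, a secreted Wnt inhibitor, was at −1.74 (adjusted p = 0.628).

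Bone and connective tissue lists had negative medians. No member of any of these lists passed, over all genes or adjusted over the list alone, and each set's adjusted p with an estimated correlation is given second. All 18 osteoblast and bone matrix genes were negative (median −0.56, set 8.11e-05; adjusted p = 0.557 with an estimated correlation), such as Alpl, the alkaline phosphatase of mineralising cells (−0.77, adjusted p = 0.628). All 16 cartilage genes were negative (median −1.19, set 1.96e-08; adjusted p = 0.511 with an estimated correlation), with Col2a1 at −1.20 and Sox9 at −1.28. The cartilage list's mean log2 level was −2.22 in Ti+I-OG replicate 3 and 0.39 and 0.54 in the other Ti+I-OG libraries, and its median was −0.71 without that library. Osteocyte genes (median −0.37, set 0.00397; adjusted p = 0.511 with an estimated correlation), with Dmp1 at −0.40, were negative for 10 of 11. Tendon genes (−0.50, set 0.000889; adjusted p = 0.611 with an estimated correlation) were negative for 13 of 14 and fibrillar matrix genes (−0.39, set 6.67e-06; adjusted p = 0.511 with an estimated correlation) for 19 of 20. The RANKL axis (−0.19, set 0.0185; adjusted p = 0.511 with an estimated correlation) and bone morphogenetic protein and TGF-beta genes (−0.26, set 0.000809; adjusted p = 0.511 with an estimated correlation) were lower as sets, and the osteoclast list was not (−0.18, adjusted p = 0.113), with no called member of its 16, also adjusted over the list alone.

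Upward lists were those of red cells, platelets, proliferation and mitochondria. All 19 erythroid genes were positive (median 0.44, set 1e-07; adjusted p = 0.557 with an estimated correlation), with Hbb-bs at 1.21 and Alas2, the first enzyme of erythroid haem synthesis, at 0.89 (adjusted p = 0.628 each), where the globin share was 15.6% against 8.04%. All 12 megakaryocyte genes were positive (0.44, set 0.00397; adjusted p = 0.627 with an estimated correlation), but the call ended without Ti replicate 2 (adjusted p = 0.809) or Ti+I-OG replicate 3 (0.334), where the list's mean log2 level was −1.48 and 0.91, against −0.28 and 0.45 in the other Ti and −0.20 and −0.32 in the other Ti+I-OG libraries. Also positive were 22 of 25 proliferation genes (0.16, set 0.000465; adjusted p = 0.619 with an estimated correlation), 37 of 38 oxidative phosphorylation genes (0.20, set 7.37e-06; adjusted p = 0.557 with an estimated correlation) and 13 of 15 oxidative stress genes (0.13, set 0.0144; adjusted p = 0.557 with an estimated correlation). No member of these 5 lists passed, also adjusted over the list alone. Fold change and transcript length correlated at −0.325 (Spearman, across genes), and with a length correction the oxidative phosphorylation (adjusted p = 0.187) and oxidative stress lists (0.0523) did not pass. Of 30 skeletal muscle genes Myh7, Tnni1 and Tnnt1 rose, also adjusted over the list alone, and the set did not pass (adjusted p = 0.0989), with a median of −0.08 and a mean of 0.16. It passed upward on FPKM (0.00373) and without Ti replicate 1 (0.0166), Ti replicate 2 (7.03e-06) or Ti+I-OG replicate 1 (0.00676). The other 15 lists did not pass and had no called member, also adjusted over the list alone: macrophage (adjusted p = 0.202), alternative macrophage activation (0.0913), neutrophil (0.391), B lineage (0.453), plasma cell (0.829), T and NK cell (0.829), mast cell and eosinophil (0.172), adipocyte (0.829), endothelial (0.829), Schwann cell (0.359), skin (0.91), interferon-stimulated (0.829), immediate early (0.388), and glycolysis and irisin-related genes (0.635 each). Median and mean had opposite signs in the inflammatory, plasma cell, T and NK cell, interferon-stimulated and irisin-related lists, and the adipocyte list was directed downward with a median of 0.05 and a mean of 0.08, passing without Ti+I-OG replicate 3 (0.00532). In the 31 lists with no member passing edgeR's test, 70 of 580 genes had an unadjusted p under 0.05, and DESeq2, limma-voom and limma-trend on FPKM called 0.

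In this comparison 13 of the 32 lists passed the preset set test, 5 upward and 8 downward, against 0 with an estimated correlation and 0 by the fry test (smallest adjusted p = 0.511 and 0.363). Of 324 KEGG pathways 40 passed, 22 upward and 18 downward, and none with an estimated correlation (smallest adjusted p = 0.564). Without Ti replicate 2 the Wnt (0.382), tendon (0.157), osteocyte (0.0595), RANKL (0.0595) and proliferation (0.444) list calls ended too, as did the tendon (0.0789) and RANKL (0.184) calls without Ti+I-OG replicate 3. The pathway count was 62 and 26 without Ti replicates 2 and 3 and 23, 11 and 90 without Ti+I-OG replicates 1, 2 and 3. Without Ti replicate 1 no gene passed edgeR's test, with 441 at an unadjusted p under 0.05 and Myh7 at an adjusted p = 0.0588; 5 genes passed without Ti replicate 2, 3 of them among the 6, and 1 without Ti replicate 3, and 2, 1 and 1 without Ti+I-OG replicates 1, 2 and 3. DESeq2 called 16 genes. After a length correction Myl2 (1.82, adjusted p = 0.0824) and Tnnt1 (1.36, adjusted p = 0.226) no longer passed, and on FPKM Angptl4 did not (0.74, adjusted p = 0.109).

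The third comparison set hydrogel-treated tibiae against naive ones. The rises and falls ranked here are the largest among genes that met the naming rule. Slow-fibre genes were again among the most increased: Myh7 rose by 6.23 (SE 0.477, adjusted p = 0.000163), Tnnc1 by 4.90 (SE 0.628), Myl3 by 4.66 (SE 0.415) and Myl2 by 4.10 (SE 0.323). Tnni1 also passed, with 290 counts in Ti+I-OG and 5 in naive, a ratio of 79.3 (95% counting interval 33.6 to 246). Mmp12 rose by 3.58 (SE 0.589, adjusted p = 0.012), Tnmd by 3.50 (SE 0.335) and Acp5 by 1.40 (SE 0.209, adjusted p = 0.00785), to 766 ± 210 CPM. The falls were led by Lipg (−3.02, SE 0.546; −1.86 without naive replicate 3, not passing without Ti+I-OG replicate 1 or 2, adjusted p up to 0.0876), Ggt1 (−2.60), the neutrophil chemokine receptor gene Cxcr1 (−2.29), Prok2 (−2.22), Kcna3 (−1.90; −2.80 without Ti+I-OG replicate 3, and not passing in 4 of 6 fits with a library left out), Mgam (−1.77) and Ifitm1 (−1.75). Cidea, a lipid droplet gene, passed with 95 counts against 3, a ratio of 43.3 (interval 14.4 to 214). Ti+I-OG replicate 3 held 75 of its 95 counts, and the call ended without that library (log2 fold change 3.52, adjusted p = 0.1003) and in 4 of the 5 other fits with a library left out. Ccl21b and Zbed6, which share sequence or overlap with other genes, were also among the largest changes and are uncertain. So are Alas2, Mb, Ndufa2 and Slc2a1, which overlap a gene on the opposite strand, and Egfl7 and Itgam, which overlap one on the same strand.

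In total 1174 genes changed, 545 higher and 629 lower in Ti+I-OG, 389 of them at least 2-fold, and the groups did not overlap for 35.5% of genes, where chance gives 10%. The change went with transcript length: the Spearman correlation across genes, which are not independent replicates, was −0.402, and genes longer than 5000 bases made up 55.3% of lower genes against 15.2% of all tested genes.

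Among bone and connective tissue lists, 9 of 14 tendon, 7 of 20 fibrillar matrix, 6 of 11 osteocyte, 6 of 16 osteoclast, 2 of 18 osteoblast and 1 of 16 cartilage genes rose over naive. None of these lists passed with an estimated correlation. Of 16 osteoclast genes 6 rose and 10 did not pass (7 rose adjusted over the list alone), with Ctsk at 1.37 and the fusion gene Dcstamp at 1.61. The set passed at 0.00786, with adjusted p = 0.557 with an estimated correlation, and did not pass with the replicate number as a block (adjusted p = 0.0514). The larger KEGG pathway of osteoclast differentiation did not pass and was directed downward (adjusted p = 0.0585, 4 rose and 7 fell). Of 18 osteoblast genes Tnn (2.58) and Bmp3 (1.16) rose and 16 did not pass (10 rose adjusted over the list alone; set 6.68e-05, adjusted p = 0.557 with an estimated correlation), and Bglap was at 1.02 (SE 0.603, adjusted p = 0.276), with naive replicate 3 low as above. Of 11 osteocyte genes 6 rose, with Dmp1 at 0.69, Mepe at 1.10 and Sost at 1.06 (10 higher and 1 lower adjusted over the list alone; set 0.000111, adjusted p = 0.478 with an estimated correlation). Of 16 cartilage genes Comp rose (1.28), also adjusted over the list alone, and the set did not pass (adjusted p = 0.439), but did at 1.49e-05 without Ti+I-OG replicate 3. Of 14 tendon genes 9 rose (14 adjusted over the list alone; set 4.2e-10, adjusted p = 0.478 with an estimated correlation), among them Thbs4 (2.69), Kera (3.47) and Angptl7 (1.78). Of 20 fibrillar matrix genes 7 rose (12 adjusted over the list alone; set 3.21e-05, adjusted p = 0.478 with an estimated correlation), with Col3a1 at 2.74 and Mmp2 at 1.18. In the bone morphogenetic protein list Bmp4 rose (1.41), also adjusted over the list alone (set adjusted p = 0.203).

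Among the pathways named for the study, Fermt2 (0.83) rose among 39 integrin and focal adhesion genes and Itgam, the myeloid integrin αM chain, fell by 0.87 (adjusted p = 0.0472), with none adjusted over the list alone. Itgav was at 0.56 (adjusted p = 0.0771, and 0.0192 with the replicate number as a block) and Itgb5 at 0.19 (adjusted p = 0.384), and the set test (adjusted p = 0.995) was directed downward where median and mean were 0.01 and 0.04. Of 57 Wnt genes 6 rose, including Wnt16 (2.96), Sfrp2 (2.93) and Dkk3 (1.69), and Apc (−0.73) and Gsk3b (−0.63) fell (8 and 2 adjusted over the list alone; set 0.0109, adjusted p = 0.557 with an estimated correlation). Of 37 inflammatory genes the chemokine gene Ccl8 rose (1.84) and Tlr4 fell (−0.73), with the same counts adjusted over the list alone (set adjusted p = 0.676), and Tnf (−0.13), Il1b (−0.14) and Il6 (−0.76) did not pass. Of 16 RANKL axis genes Trem2 rose (0.86) and Traf6 (−0.58) and Sema3a (−1.09) fell (2 and 2 adjusted over the list alone; set adjusted p = 0.724), with Tnfsf11 at 0.26 and Tnfrsf11b at 0.74, of which Tnfrsf11b passed only with the replicate block (adjusted p = 0.0388). No irisin-related gene passed, 3 did when adjusted over the list alone (set adjusted p = 0.153), and Fndc5 was at 1.67 (SE 0.551, adjusted p = 0.0739, and 0.0215 with the replicate block).

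In blood lineages, 5 of 19 erythroid genes rose (10 adjusted over the list alone). They were Alas2 (1.01) and the globin genes Hbb-bs (1.58), Hbb-bt (1.55), Hba-a2 (1.52) and Hba-a1 (1.42), near-identical copies whose single values are uncertain. The globin share was 15.6% against 6.15%, and the set passed at 7.25e-05, with adjusted p = 0.557 with an estimated correlation. Of 18 neutrophil genes Cxcr2 (−0.96) and Csf3r (−0.61) fell (6 adjusted over the list alone; set 0.00194, adjusted p = 0.557 with an estimated correlation). Of 18 macrophage genes Trem2 and Cd68 (0.52) rose (7 adjusted over the list alone; set 0.00494, adjusted p = 0.478 with an estimated correlation). Of 11 alternative activation genes Cd209a (1.61) and Retnla (2.3) rose and Il4ra fell (−0.93; 4 and 1 adjusted over the list alone; set adjusted p = 0.173). The mast cell protease genes Mcpt4 (3.08), Tpsb2 (3.22) and Cma1 (2.61) rose among 12 mast cell and eosinophil genes, also adjusted over the list alone (set adjusted p = 0.533). No B lineage gene of 15 passed, also adjusted over the list alone (set 0.00232, adjusted p = 0.586 with an estimated correlation), and none of the megakaryocyte (set adjusted p = 0.533) or T and NK cell genes did (0.875). Sdc1 rose (0.93) among 10 plasma cell genes, with 2 adjusted over the list alone (set adjusted p = 0.836).

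Of 30 skeletal muscle genes 5 rose and all were positive (17 rose adjusted over the list alone; set 2.4e-08, adjusted p = 0.557 with an estimated correlation), namely Myh7, Tnni1, Tnnt1, Mb (1.56) and Mylpf of fast fibres (1.67). Of 19 adipocyte genes 5 rose, Cidea, Lpl (1.43), Cidec (2.12), Cfd (2.16) and Fabp4 (1.33), with 10 higher and 1 lower adjusted over the list alone (set 0.00194, adjusted p = 0.557 with an estimated correlation). The adipocyte list's mean log2 level was 1.21 in Ti+I-OG replicate 3 against −0.37 and 0.20 in the other Ti+I-OG libraries, and the set did not pass without it (adjusted p = 0.0913). Of 38 oxidative phosphorylation genes 9 rose, such as Uqcrq (0.71) and Ndufa2 (0.94), and all were positive (22 rose adjusted over the list alone; set 6.89e-09, adjusted p = 0.49 with an estimated correlation). Gpx3 (1.12), Gpx1 (0.82), Nqo1 (0.76) and Cat (0.59) rose among 15 oxidative stress genes (10 adjusted over the list alone; set 0.0006, adjusted p = 0.49 with an estimated correlation). Of 24 interferon-stimulated genes 3 fell, Oas2 (−1.43), Oas3 (−0.59) and Ddx58 (−0.49) (3 adjusted over the list alone; set 0.0379, adjusted p = 0.557 with an estimated correlation, and 0.0672 with the replicate block). Slc2a1, a glucose transporter gene, fell by 0.80 among 18 glycolysis genes (1 higher and 1 lower adjusted over the list alone; set 0.0291, adjusted p = 0.557 with an estimated correlation). Egfl7 rose (0.86) among 15 endothelial genes, with none adjusted over the list alone (set adjusted p = 0.153), and Pmp22 (0.93) among 10 Schwann cell genes, also adjusted over the list alone (0.11). The proliferation (0.676), immediate early (0.25) and skin (0.698) lists had no called member, also adjusted over the list alone. In the 7 lists with no member passing edgeR's test, 23 of 102 genes had an unadjusted p under 0.05, and DESeq2 called 5, limma-voom 15 and limma-trend on FPKM 3.

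Of the 32 lists 16 passed, 13 upward and 3 downward, none with an estimated correlation. Of 324 KEGG pathways 60 passed, 26 upward and 34 downward, none with an estimated correlation (smallest adjusted p = 0.629). The directional fry test passed 48 pathways and 8 lists. These lists were osteoclast, osteocyte, tendon, fibrillar matrix, macrophage, alternative macrophage activation, oxidative phosphorylation and oxidative stress. In this comparison same-numbered libraries met the bar of 0.1, which does not establish that the numbers pair the samples. With the number as a block 3450 genes changed in place of 1174, or 2102 with a length correction as well. The length correction alone left 353. With it 31 of the 74 named calls ended, among them those of the 4 globin genes, Comp, Trem2, Cd68, Retnla, Itgam, Ccl8, Csf3r, Kcna3, Tpsb2, Cma1, Oas3, Ddx58, Mylpf, Cidea, Fabp4, Cfd, Gpx1, Nqo1, Cat, Uqcrq, Ndufa2, Egfl7, Pmp22 and Ccl21b. Genes that fell against their list's direction, such as Apc, Gsk3b, Tlr4, Traf6 and Sema3a, were not among the 74 and were not checked for length in this way. On FPKM 2051 genes changed, 16.4% of them higher against 46.4% in the counts, where the median of all genes lay at −0.16. The balance turned with limma-voom, where 55.1% of 3056 genes were higher, and without Ti+I-OG replicate 2, where 62.7% of 59 were. The count was 369, 2119 and 187 without naive replicates 1, 2 and 3 and 156, 59 and 400 without Ti+I-OG replicates 1, 2 and 3. In all 6 of these fits 20 of 74 called genes chosen for naming passed, among them Myh7, Tnni1, Tnmd, Acp5, Col3a1, Sfrp2 and Ifitm1.

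**Figure D3:**
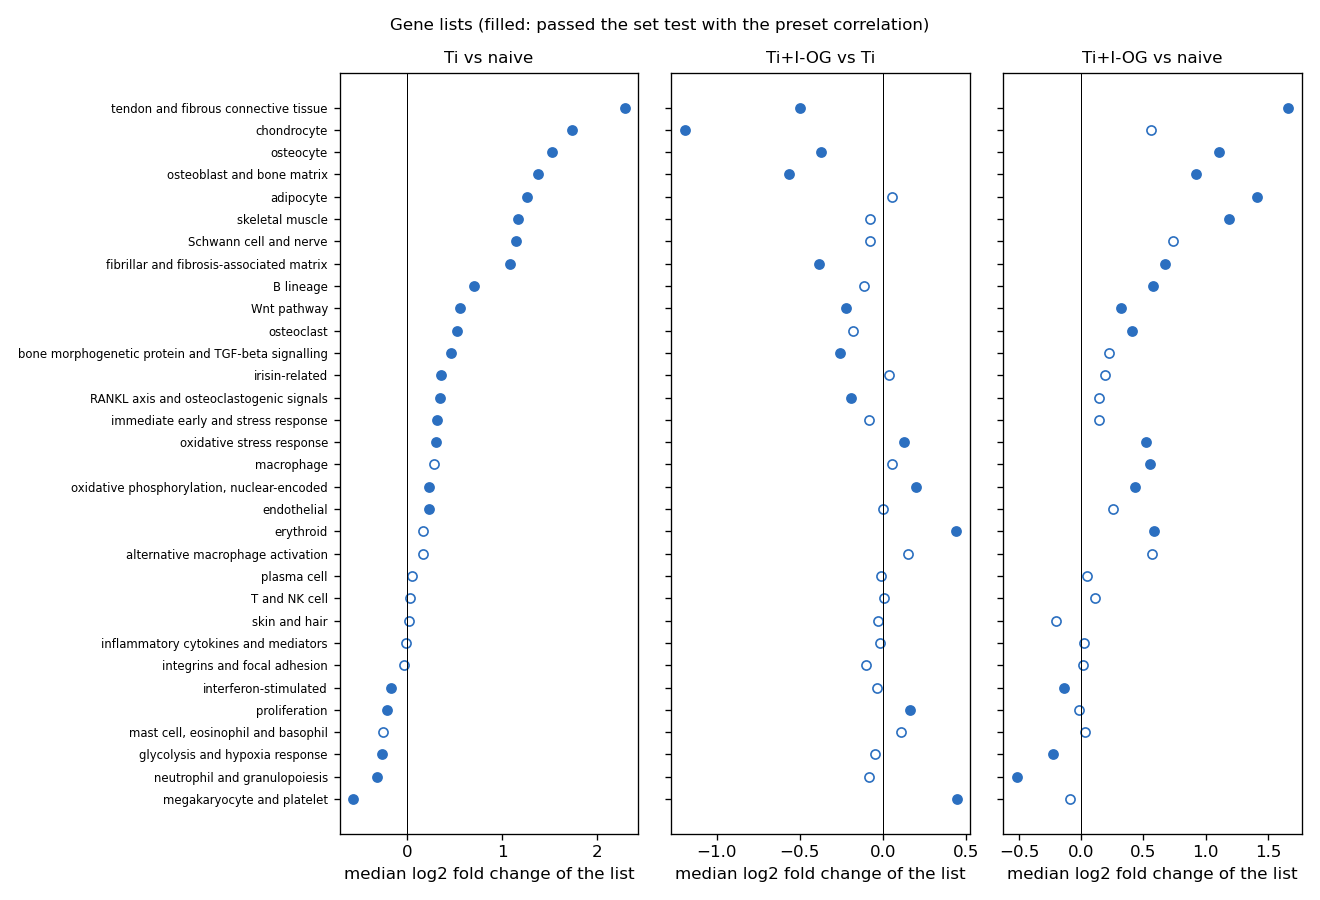
Median log2 fold change of the 32 gene lists (horizontal axes, scaled separately) in the 3 comparisons; filled points passed the set test with a preset correlation of 0.01, and none passed with an estimated correlation. The tendon list had medians of 2.29, −0.50 and 1.67 in Ti vs naive, Ti+I-OG vs Ti and Ti+I-OG vs naive.

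Across the 3 groups 820 genes differed by edgeR's F test. Genes such as Tnmd, Ctsk and Acp5 that rose in Ti were also higher than naive in Ti+I-OG: 255 genes rose in both comparisons with naive, where independent lists would share 22.1, and 246 fell in both, where they would share 15; none went in opposite directions. Unchanged groups simulated against the shared naive libraries gave an overlap of 0 in 100 draws, a value that leaves out real effects and does not measure what the shared libraries add. As 3 shared libraries cannot be split into parts of at least 2, part of the overlap may come from them. The log2 fold changes of these comparisons correlated at 0.817 (0.493 simulated), with a covariance of 0.293 against a simulated 0.0468, a difference of 0.246. Angptl4 alone was called in opposite directions, lower in Ti than in naive (−0.90, SE 0.133, adjusted p = 0.00626) and higher in Ti+I-OG than in Ti, where independent lists would share 0.143 genes and the simulation 0.02; the call in Ti+I-OG vs Ti was absent on FPKM, in the 6 libraries alone (adjusted p = 0.0686) and in each of the 6 fits without a Ti or Ti+I-OG library (adjusted p = 0.0825 to 0.168). Tnni1, Myl2 and Myl3 were called upward in both steps. Of the 914 genes changed in Ti vs naive, 690 (75.5%) had the opposite sign in Ti+I-OG vs Ti, a direction that the shared Ti libraries also favour. For that pair the correlation was −0.348 (−0.496 simulated) and the covariance −0.0767 against a simulated −0.0472, a difference of −0.0295. Genes higher in Ti had a median log2 fold change of 1.29 in Ti and 0.91 in Ti+I-OG, both against naive, and lower genes −0.81 and −0.83. These genes were chosen by their change in Ti, which favours larger values there, so the medians do not measure a reversal. The F test count was 183, 1326 and 167 without naive replicates 1, 2 and 3, 139, 294 and 1729 without Ti replicates 1, 2 and 3, and 191, 185 and 496 without Ti+I-OG replicates 1, 2 and 3.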

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

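The robust fit, the normalisation without erythroid genes and the length corrections were chosen after seeing the data; the other alternatives were planned. Among named genes 2942 values under alternatives kept their side of the threshold, 521 no longer passed and 30 came to pass; no called gene changed sign, and 25 of 3493 values changed sign while passing in neither fit. The cause of these shifts was not tested. The settings for a table with FPKM alone (scaled or quantile-normalised FPKM, a pseudocount of 0.1) did not apply, because counts were there.

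For Ti vs naive (914 genes) DESeq2 gave 1859, limma-trend on FPKM 566, limma-voom 2461, the 6 libraries alone 357, a 2-fold minimum 492 and single libraries left out 100 to 1999. With the replicate block it gave 2968 (50.6% higher against 62.9%), and 2726 with the length correction too. For Ti+I-OG vs Ti (6 genes) DESeq2 gave 16, a mean of at least 100 counts 3, and libraries left out 0 to 5. Of the 6, Angptl4 did not pass in the 6 libraries alone (adjusted p = 0.0686) and Tnni1 not with block and length correction (0.0509). For Ti+I-OG vs naive (1174 genes) DESeq2 gave 2439, FPKM 2051, limma-voom 3056, the length correction 353, the 6 libraries alone 770, a 2-fold minimum 389, the replicate block 3450, the block with the length correction 2102, and libraries left out 59 to 2119. For the F test (820 genes) DESeq2 gave 2473, limma-voom 3017, the length correction 427, a 2-fold minimum 438, the replicate block 3313, the block with the length correction 2306, and libraries left out 139 to 1729. Genes called in opposite directions by Ti and by Ti+I-OG (1) were 2 with the replicate block, 7 with DESeq2, 0 on FPKM and 0 to 1 with libraries left out.

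Same-numbered libraries correlated at −0.0238, 0.333 and 0.239 between naive and Ti and at 0.0739, 0.203 and 0.220 between Ti and Ti+I-OG. Not all of these met the bar of 0.1, although all but naive replicate 1 with Ti correlated best with their own number. The block gave 9 genes (7 higher, 2 lower) in Ti+I-OG vs Ti, brought Ighg1 (−2.15) past the threshold there and Fndc5, Tnfrsf11b and Bglap in Ti vs naive, and, among lists, ended only the osteoclast and interferon-stimulated calls of Ti+I-OG vs naive.

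With an estimated correlation the passing lists went from 23, 13 and 16 to 0, 0 and 0, and the KEGG pathways from 34, 40 and 60 to 0, 0 and 0. The directional fry test passed 7, 0 and 8 lists, and the mixed test 21, 0 and 23. Among KEGG pathways the directional test passed 8, 0 and 48 and the mixed test 272, 2 and 317. The length correction ended 5 list calls, named in the report, and brought past the threshold neutrophil genes in Ti+I-OG vs Ti (0.00900, downward) and, in Ti+I-OG vs naive, the endothelial (0.00844), Schwann cell (0.0376), bone morphogenetic protein (0.0166) and irisin-related (0.0312) lists. On FPKM, Schwann cell (0.0612), immediate early (0.114) and glycolysis (0.0612) calls ended in Ti vs naive and interferon-stimulated (0.0876) and glycolysis (0.0598) calls in Ti+I-OG vs naive, while macrophage genes passed in Ti vs naive (0.0180), mast cell (0.0371) and muscle genes (0.00373) in Ti+I-OG vs Ti, and cartilage genes in Ti+I-OG vs naive (0.0132). With libraries left out lists ranged over 16 to 21, 11 to 14 and 14 to 19, and pathways over 23 to 44, 11 to 90 and 50 to 71. In Ti vs naive the irisin-related call ended without every library but Ti replicate 3 (adjusted p up to 0.138), and without Ti replicate 2 so did the neutrophil (0.0774), megakaryocyte (0.200), proliferation (0.135) and interferon-stimulated (0.111) calls. The RANKL, endothelial, immediate early, oxidative stress, and glycolysis calls also ended in some of these fits (up to 0.180, 0.169, 0.122, 0.123 and 0.212), and erythroid genes passed without naive replicate 2 (0.00157). In Ti+I-OG vs Ti, leaving out Ti replicate 2 ended the Wnt (0.382), tendon (0.157), osteocyte (0.0595), proliferation (0.444) and megakaryocyte (0.809) calls, and muscle genes then passed (7.03e-06), as they did without Ti replicate 1 (0.0166) or Ti+I-OG replicate 1 (0.00676). Leaving out Ti+I-OG replicate 3 ended the tendon (0.0789), RANKL (0.184) and megakaryocyte (0.334) calls, and integrins passed (0.00342), as they did without Ti replicate 2 (0.0401). In Ti+I-OG vs naive the osteoclast call ended without naive replicate 2 (0.0776), the Wnt call without naive replicate 3 (0.0696), the adipocyte call without Ti+I-OG replicate 3 (0.0913; downward at 0.00532 in Ti+I-OG vs Ti then) and the interferon-stimulated call without naive replicate 1 (0.219). Depth limits genes near the floor of 0.114 to 0.206 CPM, such as Tnni1 in naive.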

Other observations

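Tests on the slow-fibre genes and on connective tissue genes, and the slow and fast fibre lists themselves, were chosen only after the results were seen; the splits of the samples and the tests of the length trend were planned before theirs.

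Among KEGG pathways, none of which passed with an estimated correlation, the strongest upward set in Ti vs naive was protein digestion and absorption, which holds many collagen genes (20 of 65 rose, median 0.84, adjusted p = 4.44e-09; adjusted p = 0.126 with an estimated correlation). Oxidative phosphorylation followed (5 of 127 rose, median 0.33, adjusted p = 4.28e-08; adjusted p = 0.786 with an estimated correlation). Unlike the shorter list of such genes in Ti vs naive, this pathway still passed upward with the length correction (0.00660), as it did in Ti+I-OG vs naive (0.0290). In Ti+I-OG vs Ti it passed upward without the correction (0.0299) but not with it, where it was directed downward (0.531). ECM-receptor interaction came next (21 of 76 rose, median 0.62, adjusted p = 5.07e-07; adjusted p = 0.497 with an estimated correlation), and was directed downward in Ti+I-OG vs Ti (median −0.20, adjusted p = 0.000514; adjusted p = 0.687 with an estimated correlation). Ribosome genes led the upward sets in Ti+I-OG vs Ti (132 genes, median 0.27, adjusted p = 3.54e-14; adjusted p = 0.687 with an estimated correlation) and in Ti+I-OG vs naive (median 0.48, 14 rose, adjusted p = 9.82e-15; adjusted p = 0.629 with an estimated correlation). Fold changes went with transcript length in these comparisons (Spearman correlations across genes of −0.325 and −0.402), and with the length correction the ribosome set's adjusted p was 0.00200 and 0.108. Wnt signaling (adjusted p = 0.0593), NF-kappa B signaling (0.109, but 0.0344 downward with the length correction) and TNF signaling (0.312) did not pass in Ti+I-OG vs Ti, while focal adhesion was lower as a set (0.00478; adjusted p = 0.687 with an estimated correlation, and 0.116 with the length correction). NF-kappa B signaling was lower as a set in Ti+I-OG vs naive (0.00598, and adjusted p = 0.629 with an estimated correlation). Osteoclast differentiation (121 genes) passed in no comparison and was directed downward in each. The list of 16 osteoclast genes was directed upward in both comparisons with naive. The pathway's adjusted p was 0.462 in Ti vs naive (median −0.08, mean 0.02), 0.0857 in Ti+I-OG vs Ti and 0.0585 in Ti+I-OG vs naive (median −0.14, mean −0.08).

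The 6 libraries of each pairwise comparison can be split in 10 ways, too few for a share under 0.05. The real split gave 914 genes in Ti vs naive and the highest other split 0; the values were 6 and 0 in Ti+I-OG vs Ti, and 1174 and 1 in Ti+I-OG vs naive, so the real one was in each case the 1 split with as many genes. In Ti+I-OG vs naive, where same-numbered libraries met the bar of 0.1, the 3 other splits that part all 3 same-numbered pairs gave 0 genes. For the F test 2 of 100 drawn splits of the 9 libraries, the real one included, gave as many genes as the real 820. This share argues against chance for this fit, but only for naive against the remaining libraries. These splits and counts leave the replicate numbers out, and with them as a block the real split gave 3313. The other split gave 1283 genes and kept the naive group whole while exchanging Ti replicate 3 with Ti+I-OG replicate 2. The next highest splits, at 487 and 461 genes, also kept naive whole. This points to a structure of naive against the remaining libraries, and the test does not bear on a difference between Ti and Ti+I-OG.

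Slow-fibre muscle genes were higher in Ti+I-OG than in Ti. More muscle of all fibre types would raise fast-fibre genes as well. The 11 fast-fibre genes had a median log2 fold change of −0.0812 (SD over genes 0.357). The 5 called slow-fibre genes were at 1.55 or more, but were taken because they passed, so this gap was largely set in advance. Over all 14 slow-fibre genes, the median log2 CPM minus the fast-fibre median was −6.41, −6.75 and −5.76 in Ti and −4.36, −5.17 and −5.01 in Ti+I-OG. Fast-fibre medians overlapped, at 8.32, 8.88 and 7.14 in Ti and 7.63, 8.44 and 8.15 in Ti+I-OG. Both kinds of muscle gene were already higher in Ti than in naive. The slow-fibre median log2 fold change there was 1.60 (6 of 14 rose) and the fast-fibre median 1.17 (1 of 11 rose). In naive the slow minus fast difference was −5.98, −6.42 and −6.50. A candidate explanation is a piece of slow-type muscle left on the Ti+I-OG bones. The 14 slow-fibre genes had a median log2 fold change of 0.785. The 9 not called, a group set by the threshold, had a median of 0.252, with 6 positive and Tnnc1 at 3.35 (SE 0.553, adjusted p = 0.132). Attached slow-type muscle cannot be told apart from a change in muscle fibre type or in expression within the bone, which remain untested. Length correction ended the calls of Myl2 and Tnnt1 (1.82 and 1.36 after it, 2.01 and 1.55 before).

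Connective tissue and bone matrix genes were higher in Ti than in naive. The low bone matrix genes of naive replicate 3 are not the whole source, as the osteoblast list kept a median of 1.01 without that library and the tendon list 2.06. For tendon genes length-dependent recovery is not the whole source either, since the tendon list's median was 2.29 after the length correction. The bone matrix list was not weighed in this way. A lower share of marrow alone would raise the other cell types alike. Tendon genes rose over 2 of 5 lists from outside marrow by more than 5 standard errors (osteocyte 1.02, SE 0.172; Schwann cell 1.39, SE 0.191). They rose by 0.743 (SE 0.366) over osteoblast, 1.12 (SE 0.591) over muscle and 0.506 (SE 0.273) over cartilage genes. The Schwann cell list had lost Sox10, Nefl, Nefm and Prph to the filter, and the osteocyte list holds Fgf23, which fell, so this test does not decide the marrow share. Marrow lists moved both ways: 15 of 15 B lineage and 13 of 19 erythroid genes were positive, and 13 of 18 neutrophil and 12 of 12 megakaryocyte genes negative. The bar of 5 standard errors was set after these values were seen and is the third form of this test; the form before it asked for more than 2 standard errors over all 5 lists, which 3 of 5 met, and left the marrow share open. A response of the bone surface to particles or to injection, or more periosteal and tendon tissue in the Ti samples, with or without less marrow, may each account for the rise and remain untested.

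Long transcripts were lower and short ones higher in Ti+I-OG than in naive (Spearman correlation across genes −0.402), and the mean correlation of a library's levels with length went from 0.254 in naive through −0.0198 in Ti to −0.309 in Ti+I-OG. Ribosome and oxidative phosphorylation genes alone do not account for it, as the correlation was −0.389 outside them, nor does GC content, given which the partial correlation with length was −0.390 over the 99.9% of genes with a value. Length-dependent recovery of transcripts, for example through RNA quality, may be the source: the trend was present in all 5 classes of mean expression, at −0.118 in the weakest and −0.593 in the strongest. Because the classes differed this much and the trend follows the groups, it cannot be told apart from a shift in cell makeup or regulation. The length correction left 353 of 1174 calls by count, 305 of them shared.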
